A study of Mus musculus with 8 samples.

How the data were processed

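RNA-seq libraries were made from cultured mouse hepatocellular carcinoma cells. The 8 libraries comprised 1 of 3H3P and 7 of 3H3PM subclones, numbered 1, 2, 3, 6, 7, 8 and 9 in the labels. Per the labels' protocols, the 3H3 line came from a liver tumour of a mouse lacking MC4R on a high-fat diet and carries an Hras mutation. 3H3P is its derivative with Trp53 knocked out by CRISPR/Cas9, with loss of p53 protein seen by western blot. 3H3PM is 3H3P with ectopic MYC, and the subclones were recovered from tumours of these cells in nude mice. Other subclones were not analysed here. Total RNA was extracted with TRIzol and had a RIN above 7, and libraries were made with a directional NEBNext Ultra kit, per the labels' protocols.

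Per the submitters' processing notes, FastQC, STAR, RSEM and DESeq2 were used with the GRCm38 (mm10) build; their versions, options and order are not given in the sources used here. The deposited files hold, per the file headers, an expected count, a TPM value, an FPKM value and transcript lengths for each of 54838 genes. The expected count deposited by the authors is RSEM's estimate, which divides reads that match several genes among them, so 3099 to 3459 genes per library had a fractional value. Values of near-identical genes such as Plac9b, Naip6, Ces1g, Gsta3 and the H2 genes therefore rest on that division. The TPM deposited by the authors was used for alternatives only, and the FPKM deposited by the authors was not tested. Deposited lengths entered no test. Gene symbols were taken from the files, and chromosome positions from the GENCODE vM21 annotation of GRCm38, in which the versioned identifiers of 14079 of the 14634 tested genes (96.2%) were found.

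Library totals ran from 12838521 to 17987068 expected counts. At this depth a gene with 0 counts in a library has an upper limit of 3 counts. Fold changes of genes with 0 counts throughout a group were computed against 3 counts over the whole group and are given as "at least". For groups with 1 to 3 counts the ratio is given with its 95% exact binomial interval. Intervals and floors cover counting error only.

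Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood F test (glmQLFit and glmQLFTest) after filterByExpr by group and TMM scaling. P-values were adjusted by the Benjamini-Hochberg method and genes with an adjusted p under 0.05 were called. All 8 libraries entered the fit. Because 3H3P had 1 library, the spread came from the 7 subclones alone (6 residual degrees of freedom) and the lone library was assumed to vary as they do. The subclones are separate isolates with 1 library each, so p-values measure the spread between isolates. CPM values are TMM-scaled and come with the SD over the subclones. The standard error of a log2 fold change was taken as its size divided by the square root of F.

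The choice of test, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. There were 24 function lists and 4 marker lists of other cell types (fibroblast and stellate, endothelial, macrophage, lymphocyte), and lists with under 5 tested members were not tested. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation and fry beside it. Named genes were Trp53, Myc, Hras, Il11 and Il11ra1, the 10 largest rises and the 10 largest falls among called genes with a mean CPM of 1 or more that moved the same way in every subclone, up to 4 members of each list with the smallest p, and the 10 genes of largest spread over the subclones at a mean CPM of 10 or more. Symbols made of Gm and digits, ending in Rik or naming pseudogenes were left out. Cdkn2a, Cd274, Cdh1 and Cdkn1a were named after their values were seen, as were the genes described in the closing observations.

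Spread over the subclones was the SD of log2 CPM (prior count 2), counted where above 1 among genes with a mean CPM of 1 or more. List medians of this SD were ranked among 10000 random lists matched on mean expression in 20 bins. The relation of Il11 to 10 list scores (mean log2 CPM of tested members) was measured by Pearson's r and Spearman's rho with two-sided exact permutation tests over all 5040 pairings (scipy 1.17.1, numpy 2.4.6).

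The gene test was tested on simulated data for this comparison of 1 library against 7, run on 13745 genes. It called 6% of genes simulated with a 2-fold change, 52% at 4-fold, 78% at 8-fold and 88% at 16-fold (50 genes each), with 4 calls among 14409 unchanged genes before filtering. The lone library was simulated from the subclones' mean and the fitted dispersions. The few false calls therefore do not check the assumption that this library varies as the subclones do. Far fewer genes were changed in the simulation than were called in the data, so the shares called need not carry over. A shifted simulated list had a camera p of 6.23e-16 and an unchanged one 0.242. Count profiles of all pairs of libraries were compared by chi-square to look for a library deposited more than once.

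Alternatives were size factors of DESeq2 1.42.0, library size alone, no filter, a filter of CPM 1 in at least 4 libraries, robust dispersion, an added 2-fold threshold, limma-voom, limma on log2(TPM + 1) and log2(TPM + 0.1), the DESeq2 Wald test, and leaving out each subclone in turn. Figures were drawn with matplotlib 3.10.9.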

Results

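Gene expression was measured by RNA-seq in 8 libraries of mouse hepatocellular carcinoma cells. One group was the 3H3P cells, a Trp53-knockout derivative of the 3H3 liver tumour line, with 1 library. The other was 3H3PM, given in the labels as the same cells with ectopic MYC, with 7 subclones recovered from tumours in nude mice and 1 library each. The library labelled 3H3P held 16855985 expected counts. Subclones 1, 2, 3, 6, 7, 8 and 9 held 16649414, 15649620, 17987068, 15095394, 12838521, 13709436 and 14258440. No pair of libraries agreed within sampling noise, as chi-square per degree of freedom was 11.9 to 94.1 over the 21 subclone pairs and 153 to 219 between the library labelled 3H3P and the subclones. Pearson's r of log2 CPM across genes was 0.938 to 0.980 among subclones and 0.843 to 0.886 between the library labelled 3H3P and the subclones. The first principal component (49.7% of variance) placed the library labelled 3H3P apart from every subclone, and the second (19.6%) spread the subclones.

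The genes that define the cell lines were examined first. Trp53 (ENSMUSG00000059552.13, chromosome 11, 69580359 to 69591873), the gene targeted in 3H3P, was at 212 CPM in the library labelled 3H3P and 53.9 ± 7.45 CPM in the subclones (SD, n = 7), lower in 7 of 7 subclones (log2 fold change −1.97, SE 0.18, edgeR quasi-likelihood adjusted p = 0.000322). A frameshift need not remove a transcript, so these counts do not check the knockout. Mouse Myc (ENSMUSG00000022346.15, chromosome 15, 61985391 to 61990374) was at 85.2 CPM in the library labelled 3H3P and 6.54 ± 3.58 CPM in the subclones, a log2 fold change of −3.71 (SE 0.53, adjusted p = 0.00206). Counts of the mouse gene thus gave no sign of the ectopic MYC, but they do not speak against the label if the introduced sequence went uncounted. The species of the introduced MYC is not given in the sources used here. How far a human sequence would be counted under the mouse gene was not tested. The labels are therefore used as names.

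Hras, mutated in the parental line, was at 127 CPM in the library labelled 3H3P and 81.3 ± 12.4 CPM in the subclones, with an adjusted p of 0.0687, and DESeq2 called it lower (adjusted p = 0.0478; 0.0478 to 0.109 over the alternatives). Il11 (ENSMUSG00000004371.15, chromosome 7, 4772373 to 4782859), the cytokine named in the series title, had 2 counts (0.124 CPM) in the library labelled 3H3P and 8.51 ± 11 CPM in the subclones. Its ratio was 64.4 with a 95% counting interval of 17.8 to 532. It was higher in 7 of 7 subclones, at 2.61, 0.83, 3.35, 15.2, 3.51, 31.1 and 2.98 CPM in subclones 1, 2, 3, 6, 7, 8 and 9, but the spread between subclones left it short of the threshold by edgeR (adjusted p = 0.143). DESeq2 gave Il11 an adjusted p of 0.00372, and over all alternatives it ran from 0.00372 to 0.430. Il11ra1, which encodes its receptor, was at 5.85 CPM against 8.80 ± 1.56 CPM (adjusted p = 0.283).

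**Figure D1:**
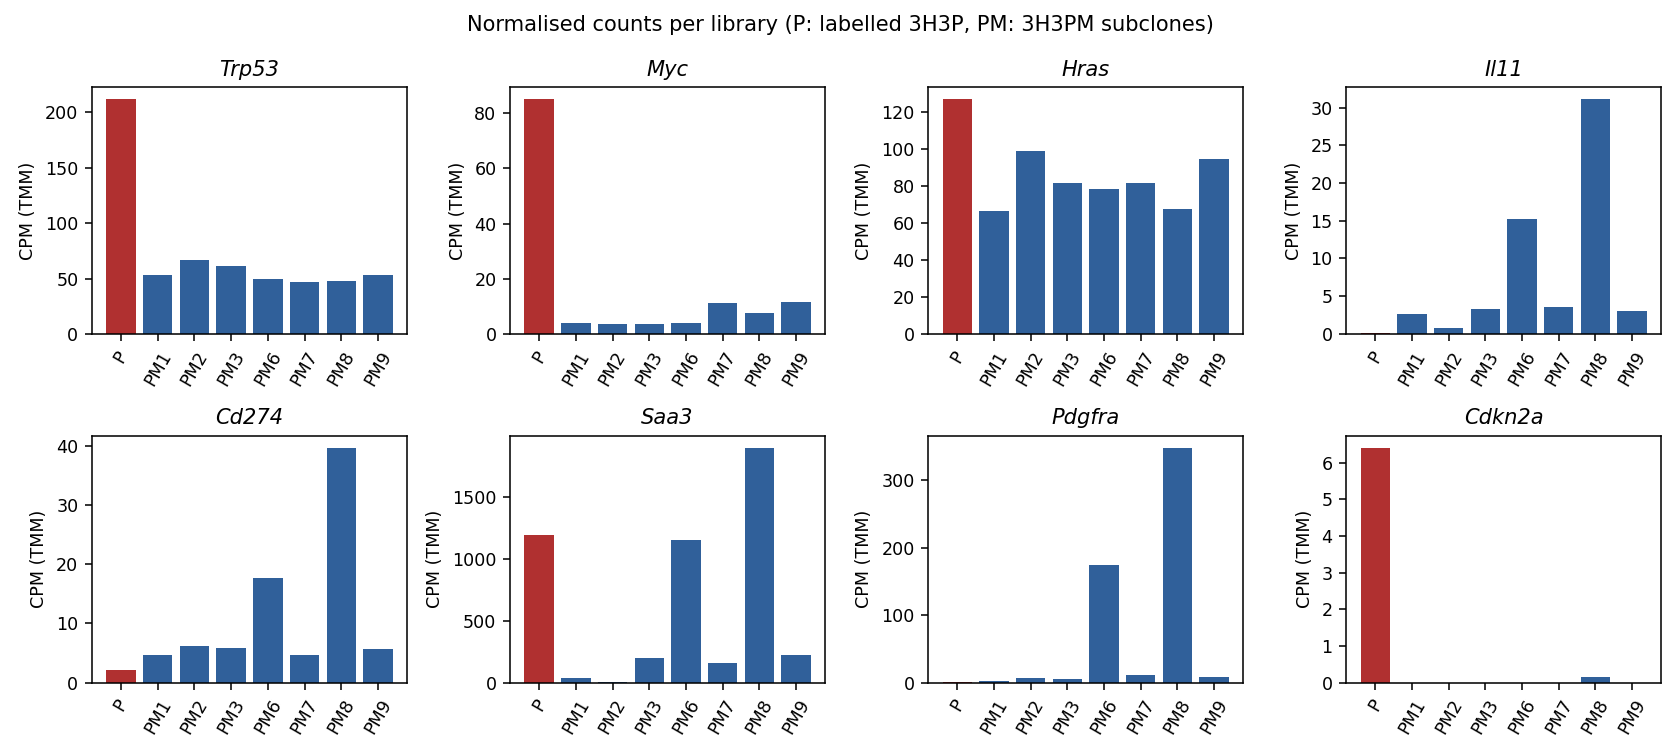
TMM-scaled CPM (y axis, linear, from 0) of 8 genes in each library (x axis; red, library labelled 3H3P; blue, 3H3PM subclones; 1 library each, no error bars). Trp53, Myc and Cdkn2a were highest in the library labelled 3H3P, while Il11, Cd274 and Pdgfra were highest in subclone 8, followed by subclone 6.

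The comparison of the subclones with the library labelled 3H3P is named in the series design. It sets cultures recovered from tumours of cells labelled 3H3PM against the line that the labels give as their origin. Genes that were abundant in the library labelled 3H3P were nearly silent in the subclones, and others were detected almost only in the subclones. Dcn, encoding the proteoglycan decorin, went from 1868 counts in the library labelled 3H3P to 1 count over all 7 subclones, a ratio of 12421 in favour of that library (95% counting interval 2227 to 490877). Cldn1, a tight junction claudin, fell by 10.12 on the log2 scale (71.9 CPM against 0.0598 ± 0.0822 CPM, adjusted p = 6.88e-05). Bst1 rose by 10.36 (0.249 CPM against 338 ± 65.1 CPM, adjusted p = 6.57e-05) and the growth factor receptor gene Pdgfrb by 7.24 (0.747 against 114 ± 20.5 CPM, adjusted p = 6.57e-05).

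Of 14634 genes tested by edgeR, 2799 were called, 1072 higher and 1727 lower in the subclones (38.3% higher). The number higher was 669 without subclone 3 and 1689 with DESeq2. At least a 2-fold change was seen in 2069 of them, 654 higher and 1415 lower. The lone library lay outside the subclones' range for all 2799 called genes and for 8455 tested genes (57.8%), where chance gives 25%. The comparison rests on 1 library, so its own variation could not be measured, and MYC, growth in mice and subcloning cannot be separated. The mitochondrial share of counts was 3.18% in the library labelled 3H3P and 1.97% to 2.31% in the subclones.

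Among the largest rises, the lectin gene Lgals7 had 0 counts in the library labelled 3H3P and 100 ± 70.8 CPM in the subclones, at least 538-fold higher (adjusted p = 0.0179). The pioneer transcription factor gene Foxa1 was at least 429-fold higher (adjusted p = 0.0210). Over the alternatives the adjusted p of Lgals7 ran from 1.92e-06 to 0.424 and that of Foxa1 from 4.34e-06 to 0.453, the top values by limma-voom, which called neither. Chdh, Cavin3, Mgp, Plac9b and Arhgdig also had 0 counts there and were at least 89.2, 79.4, 78.3, 69.0 and 37.2-fold higher. Limma-voom did not call Chdh, Cavin3 or Plac9b either (adjusted p over the alternatives 7.35e-05 to 0.292, 2.59e-05 to 0.0737 and 0.000172 to 0.280). Serpinh1, the collagen chaperone, had 1 count there and 218 ± 210 CPM in the subclones, a ratio of 3284 (95% counting interval 589 to 129728). Its adjusted p of 0.0423 rose above 0.05 without subclone 3, 6 or 9 (up to 0.0613) and ran from 1.51e-06 to 0.522 over all alternatives. Mgp, at 0.0477, was likewise lost without subclone 3, 6, 7 or 9 (up to 0.0648; 0.000191 to 0.375 over all alternatives). Ptx3, a pentraxin, had a ratio of 1077 (95% counting interval 193 to 42554) and was not called by limma-voom (7.83e-06 to 0.470).

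The largest falls included 8 genes with 0 counts in every subclone. Maob, which encodes a monoamine oxidase, was at 41.7 CPM in the library labelled 3H3P and at least 1487-fold lower in the subclones (adjusted p = 0.00312). Selp, Ces1g, Ehd3, Olfm4, Il13ra2, Nox4 and Naip6 were at least 929, 893, 712, 603, 592, 539 and 499-fold lower. Gsta3, a glutathione transferase gene, fell by 10.76 on the log2 scale (SE 0.73, adjusted p = 6.88e-05).

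Gene lists fixed before the data were examined described these changes by function. With a preset correlation, camera called 9 of 24 function lists, 2 higher and 7 lower, and with an estimated correlation it called 0, with 3 at an unadjusted p under 0.05. By fry 12 lists were called. List medians were the same with genes at 0 counts set at their bounds.

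The hepatocyte list was called lower in the subclones. Only 13 of its 32 genes were tested, so the result covers a part of the list. Of these 13 members 7 were lower and 0 higher over all genes, and 10 were lower and 1 higher when adjusted over the list alone (camera adjusted p = 5.7e-06). The albumin gene Alb was at only 3.67 CPM in the library labelled 3H3P and was not called. The call was lost with an adjusted p = 0.312 with an estimated correlation. Apob, encoding apolipoprotein B, fell from 586 CPM to 1.56 ± 2.48 CPM (adjusted p = 0.000968). Trf, encoding transferrin, fell from 688 to 10.7 ± 4.71 CPM, the transcription factor gene Foxa2 from 80.8 to 0.689 ± 0.577 CPM, and Ass1, a urea cycle gene, from 661 to 33.8 ± 17.3 CPM.

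The epithelial junction and keratin list was called lower as well, with 9 of 16 lower, 0 higher and 9 lower adjusted over the list alone (camera adjusted p = 5.7e-06, and adjusted p = 0.329 with an estimated correlation). The simple-epithelium keratin gene Krt8 fell from 543 to 29.6 ± 15.7 CPM and Krt18 from 690 to 72.4 ± 25.5 CPM, and the junction gene Tjp3 fell by 6.22 on the log2 scale. Cdh1, encoding E-cadherin and named after its value was seen, fell from 527 to 34.3 ± 24.8 CPM (adjusted p = 0.00363). The mesenchymal transition list went both ways and was not called (2 higher and 3 lower of 17, also 2 and 3 adjusted over the list alone, camera adjusted p = 0.664). Its median was −0.48 and its mean 0.48, so they differed in sign. Within it the transcription factor genes Twist2 and Snai1 rose by 5.91 and 5.04, whereas Snai2 fell by 5.95 and the receptor gene Axl fell by 1.64.

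The MYC-responsive ribosome biogenesis list was called higher, although mouse Myc itself fell. Of 30 members 14 were higher and 0 lower, and 16 were higher adjusted over the list alone (camera adjusted p = 5.31e-06, and adjusted p = 0.574 with an estimated correlation). Gnl3, which encodes nucleostemin, rose from 135 to 353 ± 19.6 CPM (log2 change 1.39, SE 0.16, adjusted p = 0.000705). Ncl, encoding nucleolin, rose by 1.13, Nle1 by 1.36 and the spermidine synthase gene Srm by 1.42. The cell cycle list was called higher with 4 of 29 members higher, 0 lower and 25 that did not pass, likewise 4 higher adjusted over the list alone (camera adjusted p = 0.00607, and adjusted p = 0.574 with an estimated correlation). The 4 were Cdc20, Top2a, Ccna2 and Plk1, with log2 changes of 1.28, 0.90, 0.99 and 0.61, and fry did not call the list (adjusted p = 0.113). Plk1 lost its call without subclone 6, 7 or 9, with adjusted p up to 0.0690 and from 0.00968 over all alternatives. Among members that did not pass, Mki67 and Cdk1 each had a log2 change of −0.04.

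The p53 target list was called lower in the subclones than in the library labelled 3H3P, in which Trp53 is stated to be knocked out. Of 26 members 11 were lower and 0 higher, and 14 were lower adjusted over the list alone (camera adjusted p = 0.000142, and adjusted p = 0.0823 with an estimated correlation). Ccng1 fell from 395 to 32.6 ± 5.75 CPM (log2 change −3.60, SE 0.21, adjusted p = 6.57e-05). Eda2r, the p53 ubiquitin ligase gene Mdm2 and Phlda3 fell, with log2 changes of −8.72, −1.42 and −1.98. Eda2r had only 11 counts over all subclones, against 764 in the library labelled 3H3P, so the size of its fall is imprecise. Cdkn1a, encoding p21, was at 114 CPM against 15.6 ± 14.9 CPM and did not pass (adjusted p = 0.0662; 0.0175 to 0.118 over the alternatives). Cdkn2a, which encodes the p16 and ARF tumour suppressors, had 103 counts in the library labelled 3H3P and 2 over all subclones, a ratio of 342 in favour of that library (95% counting interval 92.4 to 2866, adjusted p = 0.000918). DESeq2 did not call Cdkn2a (adjusted p = 0.228; 1.89e-06 to 0.228 over the alternatives). Both Cdkn genes were named after their values were seen.

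The NRF2-responsive antioxidant list was called lower, with 8 of 18 lower and 0 higher and 9 lower adjusted over the list alone (camera adjusted p = 9.1e-05, and adjusted p = 0.0876 with an estimated correlation). Gclc, for the rate-limiting step of glutathione synthesis, and Taldo1, Me1 and Osgin1 fell, with log2 changes of −2.82, −1.60, −1.47 and −3.61.

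STAT3-responsive and acute phase genes were lower in the subclones in 8 of 23 cases and higher in 0 (9 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.00963, and adjusted p = 0.574 with an estimated correlation). Il4ra, Bcl3, the oncostatin M receptor gene Osmr and the acute phase gene Orm1 fell, with log2 changes of −2.93, −1.49, −1.91 and −5.03. The list was not called with chromosome medians removed (adjusted p = 0.0560; 0.00505 to 0.574 over its alternatives). Interferon-stimulated genes were lower in 5 of 28 and higher in 0 (8 lower adjusted over the list alone, camera adjusted p = 0.00963, and adjusted p = 0.574 with an estimated correlation), and Bst2, Trim30a, Rtp4 and Ifih1 had log2 changes of −2.26, −6.84, −2.19 and −2.27. Ifih1 lost its call without subclone 3 (adjusted p = 0.0526; 0.00690 to 0.110 over the alternatives). TGF-beta-responsive genes were lower in 4 of 16 and higher in 0 (5 lower adjusted over the list alone, camera adjusted p = 0.0432, and adjusted p = 0.554 with an estimated correlation). These were the integrin gene Itgb6, the receptor genes Tgfbr2 and Tgfbr1, and Id2, with log2 changes of −4.68, −1.16, −1.23 and −1.15. The list was not called without subclone 1, 2 or 3, with adjusted p of 0.0560, 0.0503 and 0.0510 (0.0125 to 0.554 over its alternatives). Id2 lost its call without subclone 1, 3, 6, 7 or 9, with adjusted p up to 0.0752 and from 0.0129 to 0.122 over the alternatives.

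**Figure D2:**
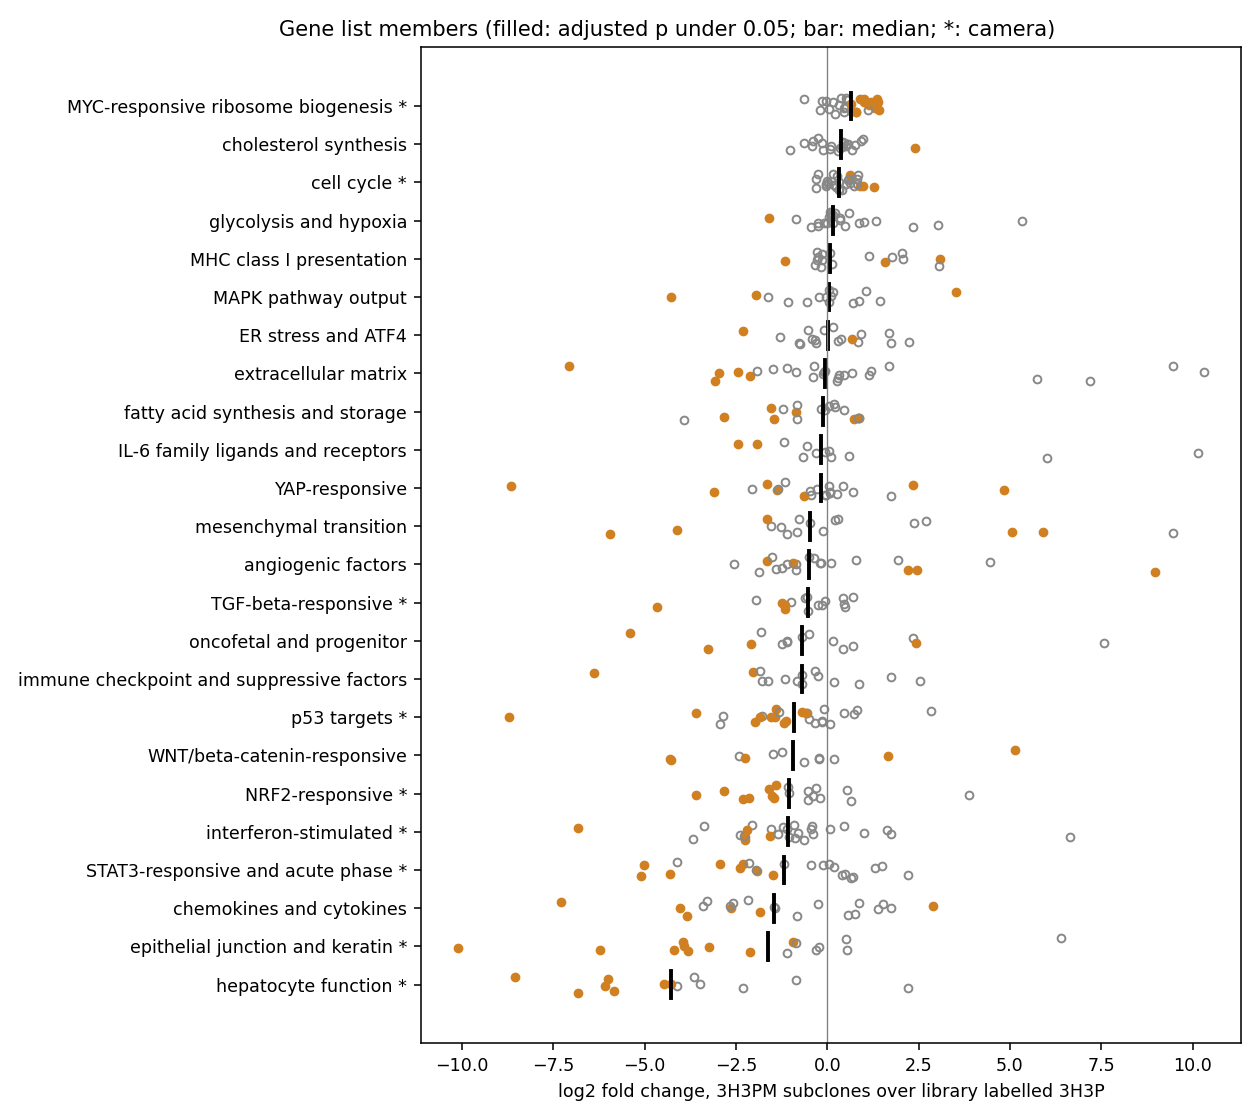
Log2 fold change of each tested member (x axis, points) of the 24 function lists (y axis), subclones over the library labelled 3H3P, ordered by list median (black bar). Filled points were called by edgeR, asterisks mark the 9 lists called by camera at the preset correlation, and genes with 0 counts in a group are drawn at their fitted value, which is no bound.

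Of 17 MHC class I presentation genes 2 were higher and 1 lower, with the same counts adjusted over the list alone (camera adjusted p = 0.361). The class I heavy chain gene H2-K1 rose from 120 to 361 ± 71.6 CPM (adjusted p = 0.00865) and the peptide transporter gene Tap2 rose by 3.09, while B2m fell by 1.16. The call of B2m, at an adjusted p of 0.0435, was lost without subclone 1, 3, 7 or 9 (up to 0.0743; 0.0199 to 0.0807 over the alternatives). Limma-voom did not call Tap2 (adjusted p = 0.0986; 0.000129 to 0.0986 over the alternatives). Among immune checkpoint and suppressive factors 2 of 15 were lower and 0 higher, also 2 adjusted over the list alone (camera adjusted p = 0.0634). The list was called by fry (adjusted p = 0.0281), with library size alone (0.0477) and without subclone 6 (0.0452) or 8 (0.0249), with adjusted p of 0.0249 to 0.574 over its alternatives. Cd47, the signal that restrains phagocytosis, and Vtcn1 fell, with log2 changes of −2.03 and −6.39. Cd274, encoding PD-L1 and named after its value was seen, was higher in 7 of 7 subclones, at 2.05 CPM against 12.1 ± 13.1 CPM, without passing the test (adjusted p = 0.249). Chemokines and cytokines were lower in 5 of 21 and higher in 1 (7 and 3 adjusted over the list alone, camera adjusted p = 0.0714), and Ccl9, Ccl7, Ccl2 and Il18 had log2 changes of −7.29, −3.84, −2.65 and −4.02. On log2(TPM + 0.1) Ccl7, Ccl2 and Il18 were not called, with adjusted p over the alternatives of 0.00240 to 0.0774, 0.00262 to 0.0691 and 0.00497 to 0.114. The list was called by fry (adjusted p = 0.0453), with library size alone (0.0477) and without subclone 7 (0.0499) or 8 (0.0438), with 0.0438 to 0.574 over its alternatives. Of 12 IL-6 family ligands and receptors 2 were lower and 0 higher, also 2 adjusted over the list alone (camera adjusted p = 0.537). These were Osmr and Il6. Il6 fell by 2.46 from 2.05 CPM, and its adjusted p of 0.0380 passed the threshold with all subclones and without subclone 8, and was up to 0.0642 without any other (0.00890 to 0.0768 over the alternatives).

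The WNT/beta-catenin, MAPK, YAP, oncofetal and angiogenic lists were not called by camera at the settings chosen first. Of them, fry called the YAP list (adjusted p = 0.0118; 0.0118 to 0.574 over its alternatives) and the oncofetal list (0.0247; 0.0247 to 0.574). With the stricter filter camera called the oncofetal list (adjusted p = 0.0364) and the WNT list (0.0492; 0.0492 to 0.628). In the WNT/beta-catenin list 3 of 12 were lower and 2 higher (4 and 2 adjusted over the list alone, adjusted p = 0.119). Ccnd1, encoding cyclin D1, fell from 961 to 49.1 ± 30.8 CPM (adjusted p = 0.00103) and Notum rose by 5.14, but limma-voom did not call Notum (adjusted p = 0.137; 8.74e-06 to 0.137 over the alternatives). For MAPK pathway output 2 of 16 were lower and 1 higher (3 and 1 adjusted over the list alone, adjusted p = 0.682), with Egr1 rising by 3.53. In the YAP list 5 of 22 were lower and 2 higher (7 and 2 adjusted over the list alone, adjusted p = 0.119), and Ankrd1 and Myof had log2 changes of −3.12 and −1.37. Oncofetal and progenitor genes were lower in 3 of 15 and higher in 1, with the same counts adjusted over the list alone (adjusted p = 0.174). Igf2 rose by 2.42 and the RNA-binding protein gene Igf2bp3 fell by 3.27. Angiogenic factors were higher in 3 of 21 and lower in 2 (3 and 3 adjusted over the list alone, adjusted p = 0.987). Angptl2, Vash2 and Thbs1 rose by 8.97, 2.21 and 2.45.

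Extracellular matrix genes were lower in 5 of 26 and higher in 0, also 5 adjusted over the list alone (camera adjusted p = 0.383), with a median of −0.08 and a mean of 0.56. Lamb3, Nid1 and Col18a1 fell, with log2 changes of −7.07, −2.44 and −2.96. Fatty acid synthesis and storage genes were lower in 4 of 18 and higher in 2 (5 and 4 adjusted over the list alone, adjusted p = 0.511), and the lipid droplet gene Plin2 and Pparg had log2 changes of −1.55 and −2.82. On log2(TPM + 0.1) Pparg was not called (adjusted p = 0.0976; 0.00643 to 0.0976 over the alternatives). Cholesterol synthesis had 1 of 22 higher and 0 lower, likewise adjusted over the list alone (adjusted p = 0.219), which was Pmvk with a rise of 2.39. Glycolysis and hypoxia had 1 of 24 lower and 0 higher, likewise adjusted over the list alone (adjusted p = 0.361), which was Hk1 with a log2 change of −1.59. ER stress and ATF4 had 1 higher and 1 lower of 18, likewise adjusted over the list alone (adjusted p = 0.846). Phgdh rose by 0.66 and the cystine transporter gene Slc7a11 fell by 2.31, with adjusted p of 0.0334 and 0.0264. Phgdh lost its call without subclone 6 or 9 (up to 0.0580; 0.00595 to 0.0580 over the alternatives) and Slc7a11 without subclone 3 (0.0514; 0.00667 to 0.0659).

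Markers of host cell types were examined because the subclones came from tumours. Of the 3 marker lists tested by camera, none was called (adjusted p = 0.303 for macrophage, 0.549 for endothelial and 0.549 for fibroblast and stellate, with 5 tested members each). With estimated correlations these were 0.563, 0.563 and 0.563. By fry the macrophage list was called, lower (adjusted p = 0.0377). The lymphocyte list had too few detected members, with at most 2 counts of any of them in a library. Lum and Dpt, abundant in fibroblasts, had 0 counts in all 8 libraries, and Ptprc, the pan-leukocyte gene, had at most 1. Of the macrophage markers, Lyz2, C1qa, C1qb and C1qc had 69, 3, 8 and 7 counts in subclone 2 and 33, 1, 0 and 3 in subclone 7, and in the other libraries Lyz2 had at most 14 and the others 0. The macrophage list genes Mrc1 and Cd74 fell from 5.23 and 5.60 CPM in the library labelled 3H3P, with log2 changes of −6.54 and −4.10, and the endothelial list gene Egfl7 rose by 2.30.

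The subclones were then compared with each other, since the series distinguishes them by number. Krt17, a keratin of basal and stressed epithelium, was at 827 CPM in subclone 2 and 336 CPM in subclone 3 and at most 7.22 CPM in the others (SD of log2 CPM 3.86). Pdgfra, a receptor gene for platelet-derived growth factor, was at 349 CPM in subclone 8 and 175 CPM in subclone 6, and at most 11.6 CPM in the others. Saa3, an acute phase gene, ranged from 8.43 CPM in subclone 2 to 1895 CPM in subclone 8 and was at 1193 CPM in the library labelled 3H3P, and the collagen crosslinking gene Lox from 0.222 CPM in subclone 8 to 38.3 CPM in subclone 7. Cthrc1, Col5a2, Fgf13, Ephb6, Bgn and Angpt1 completed the 10 genes of largest spread, with SDs of 3.18, 2.91, 2.87, 2.86, 2.72 and 2.69.

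Of 12151 genes with a mean CPM of 1 or more in the subclones, 814 (6.70%) had an SD of log2 CPM above 1, and 265 of 9128 (2.90%) did among genes with a mean CPM of 10 or more. The median SD was 0.28 and the biological coefficient of variation was 0.343. Most lists had a larger spread than random genes, with 22 of 27 above the 95th percentile of matched random lists. Chemokines and cytokines, extracellular matrix, oncofetal, STAT3-responsive, MAPK, TGF-beta-responsive, ER stress and glycolysis lists had median SDs above those of all 10000 random lists. The MYC-responsive ribosome biogenesis list lay at the 72.5th percentile, fatty acid synthesis at the 49.2nd and the endothelial list at the 2.78th. Random genes were drawn independently, whereas members of some lists varied together. The correlation estimated by camera was 0.56 for glycolysis and 0.48 for ER stress, but 0.04 for the oncofetal list. Percentiles of lists with correlated members may therefore be too extreme. Each subclone had 1 library, so differences between single subclones have no replicate check.

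**Figure D3:**
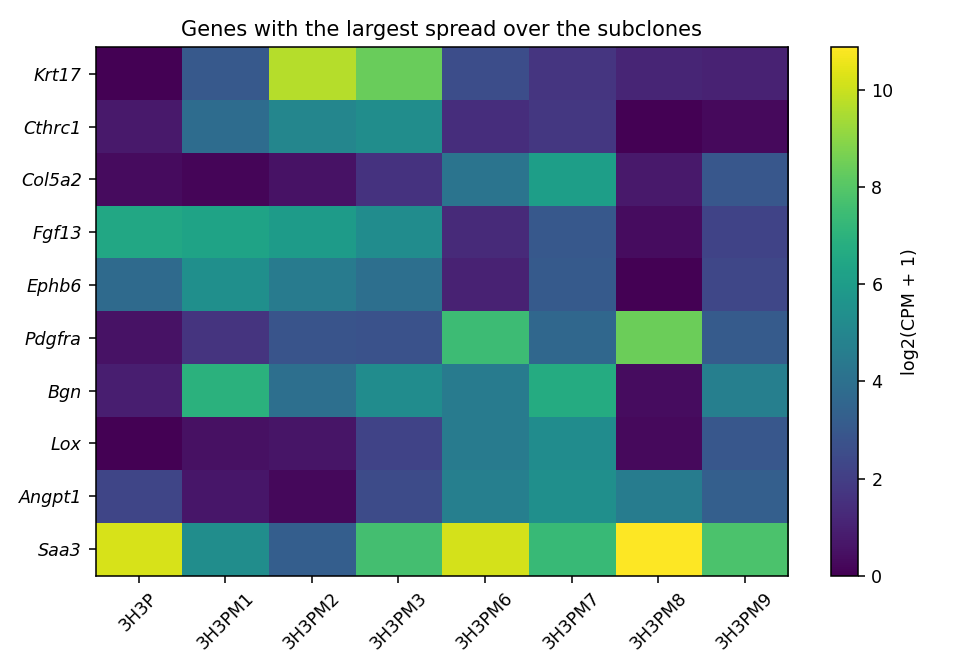
Log2(CPM + 1), by colour, of the 10 genes with the largest SD over the subclones (rows) in each library (columns; the library labelled 3H3P is shown for reference). Krt17 was highest in subclones 2 and 3, Pdgfra in subclones 8 and 6, Saa3 in subclone 8 followed by the library labelled 3H3P and subclone 6, and Lox and Col5a2 in subclone 7.

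IL11 signals through STAT3, and the series title links IL11 to immune evasion, so Il11 was set against 10 list scores over the 7 subclones. Il11 followed the STAT3-responsive and acute phase score (Pearson's r = 0.910, exact permutation p = 0.00516, adjusted p = 0.0258) and the immune checkpoint and suppressive score (r = 0.907, exact permutation p = 0.00238, adjusted p = 0.0238). By rank neither passed after adjustment (Spearman's rho = 0.786, exact permutation p = 0.0480, adjusted p = 0.120, and rho = 0.893, p = 0.0123, adjusted p = 0.0615). Without subclones 8 and 6, which lay farthest from the median of Il11, r was 0.923 for the STAT3 score and 0.533 for the checkpoint score, so the second rests in part on those subclones. Among the subclones left, subclone 2 stood apart, with Il11 at −0.058 log2 CPM and a STAT3 score of 3.07. Subclones 1, 3, 7 and 9 lay close together, at 1.45 to 1.87 and 4.05 to 4.62, so the r of 0.923 leans on subclone 2. With 1 subclone left out, 0 of 10 relations passed without subclone 2, 3, 6 or 8, where adjusted p was 0.0694 to 0.120 for the STAT3 score and 0.0556 to 0.0833 for the checkpoint score. Both passed without subclone 1, 7 or 9, so that over all alternatives adjusted p ran from 0.0139 to 0.120 and from 0.0139 to 0.0833. With 1 subclone left out r stayed within 0.887 to 0.956 and 0.814 to 0.963. These relations cover the subclones only. Between the groups the STAT3 list was lower in the subclones (8 of 23 members lower, 0 higher), although Il11 was higher in 7 of 7 subclones. The relation to the STAT3 score therefore does not extend to the library labelled 3H3P, which had 2 Il11 counts.

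The angiogenic score (r = 0.787, exact permutation p = 0.0155, adjusted p = 0.0516; rho = 0.857, p = 0.0238, adjusted p = 0.0794; r = 0.778 without the same 2 subclones) and the MHC class I score (r = 0.779, exact permutation p = 0.0286, adjusted p = 0.0714; rho = 0.929, p = 0.00675, adjusted p = 0.0615; r = 0.467 without them) did not pass. The angiogenic score passed without subclone 9 (adjusted p = 0.0463) and on log2(TPM + 1) (adjusted p = 0.0291; 0.0291 to 0.257 over the alternatives), and the MHC class I score passed without subclone 1 (adjusted p = 0.0370; 0.0370 to 0.267 over the alternatives). The extracellular matrix, mesenchymal transition, hepatocyte, interferon, cell cycle and ribosome biogenesis scores had r of 0.412, 0.330, −0.297, 0.675, −0.392 and −0.666, with adjusted p from 0.141 to 0.515 by exact permutation. Their rho values were 0.643, 0.679, −0.321, 0.643, −0.250 and −0.321, with adjusted p from 0.198 to 0.595. The largest gap in Il11 was 2.07 of a range of 5.02 log2 units (a share of 0.412), below the share of 0.5 that was set, after the values were seen, as the mark of separate clusters. Cd274 alone, outside the family of 10, had r = 0.882 (exact permutation p = 0.0417) and rho = 0.429 (p = 0.354), and r was −0.520 without subclones 8 and 6, so that relation rests on those subclones.

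**Figure D4:**
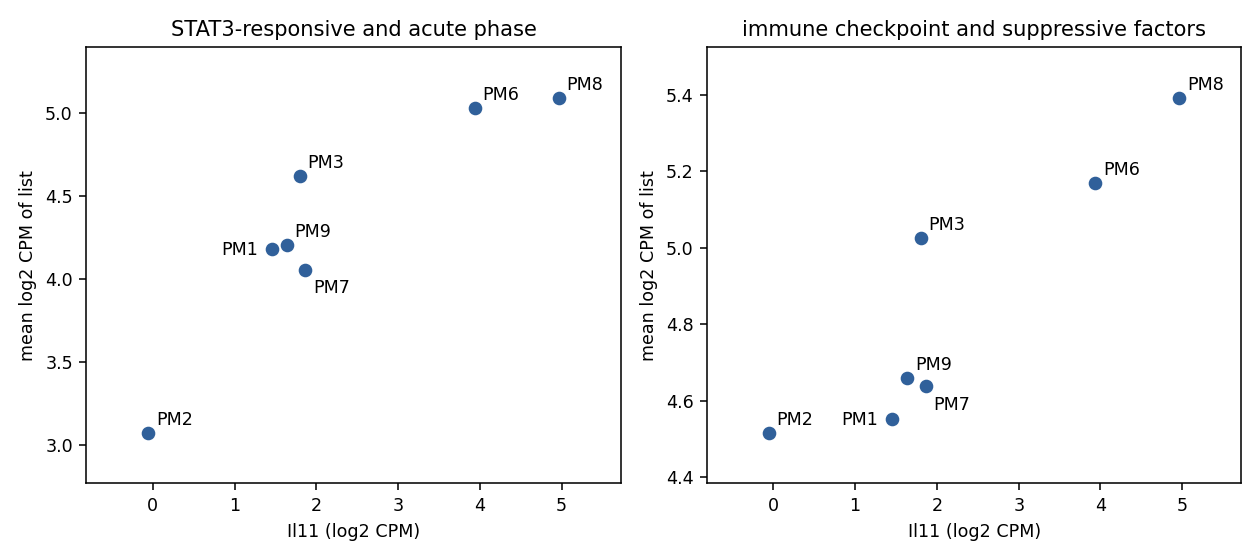
List score (y axis, mean log2 CPM of the list's tested members) against Il11 (x axis, log2 CPM) for the 7 subclones, for the STAT3-responsive and acute phase list and the immune checkpoint and suppressive list. Each point is 1 library, and subclones 8 and 6 lie highest on both axes, with subclone 2 lowest.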

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

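For each of 166 values (log2 CPM of named genes, list scores and total counts) the most extreme of the 7 subclones was compared with the range of the group, and 10 stood apart, where chance gives about 5% of groups. The 10 of 166 are close to that share, so they are no sign of more outliers than by chance. These are given as values, with the share of the range that the gap to the nearest subclone takes up.

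Car9, encoding a hypoxia-induced carbonic anhydrase, was at 0.138 CPM in subclone 9 and 1.89 to 4.97 CPM in the other subclones (gap share 0.686). Cavin3 was at 5.27 CPM in subclone 1 and 12.8 to 20.5 CPM elsewhere (0.651). Hsd17b7, of cholesterol synthesis, was at 7.60 CPM in subclone 2 and 14.7 to 21.5 CPM elsewhere (0.637). Bgn, the proteoglycan biglycan, was at 0.296 CPM in subclone 8 and 14.7 to 123 CPM elsewhere (0.626). Trim30a was at 0.611 CPM in subclone 7 and at most 0.128 CPM elsewhere (0.607), and Vwf at 1.45 CPM in subclone 9 and at most 0.329 CPM elsewhere (0.582). Both rest on few counts, 11 for Trim30a and 38 for Vwf over all subclones. The oncofetal and progenitor score was 4.79 in subclone 8 (0.577).

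For Dcn in subclone 9, Igfbp3 in subclone 6 and Cdkn2a in subclone 8 the gap share was 1, from 1, 2 and 2 counts against 0 in the other subclones, which is at the counting floor.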

How the results depend on the processing

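Removing chromosome medians before the list test and leaving subclones out of the Il11 relations were chosen after the data were seen. The edgeR gene count stayed within 1.5 times of 2799 under all alternatives run, from 1991 without subclone 3 to 3428 with DESeq2. Without 1 subclone the range was 1991 to 2985. The number of higher genes moved further, from 1072 to 669 without subclone 3 and 1689 with DESeq2. The share of called genes that were higher, 38.3% at first, was 45.2% with library size alone, 45.6% with the stricter filter, 30.0% with limma-voom, 50.3% on log2(TPM + 0.1) and 49.3% with DESeq2. No paired analysis was possible because 3H3P has 1 library.

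With an estimated correlation camera called 0 lists in place of 9. The p53 list lost its call there although its estimated correlation of −0.018 was below the preset 0.01. Correlation among its members therefore does not account for that loss, whose cause was not tested. Leaving out a subclone gave 8 to 11 lists, and removing chromosome medians gave 8, with the STAT3 list at an adjusted p of 0.0560 (0.00505 to 0.574 over its alternatives). The number of genes with an SD above 1 was 265 of 9128 (2.90%) at a mean CPM of 10 or more, against 814 of 12151 (6.70%), and 676 to 912 with a subclone left out. Relations of Il11 past the threshold numbered 2, and 0 to 3 with a subclone left out, where 6 libraries remained. The log2(TPM + 1) scale gave 3.

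Of 106 called genes among 141 named, 94 were kept with each subclone left out and 76 under every alternative, and 0 reversed. Genes that reversed had not been called. Ephb6 was at −1.53 with limma-voom, −0.87 on log2(TPM + 1), −1.53 on log2(TPM + 0.1), and −0.62 without subclone 1, −0.13 without subclone 2 and up to 0.29 without subclone 8. Lyz2 was at −0.80 with limma-voom and −0.25 on log2(TPM + 0.1). Cd68 was at −0.065 with limma-voom and −0.13 without subclone 8, up to 0.34 without subclone 9. The cause was not tested. Depth limits genes at 0 to 3 counts, whose folds are bounds or wide intervals.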

Other observations

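Some further genes differed widely between subclones. They were picked after their values were seen, and with 1 library per subclone these differences have no replicate check. Krt14, a basal keratin gene, was at 477 CPM in subclone 2, 103 CPM in subclone 9 and 43.9 CPM in subclone 3, and at most 13.2 CPM in the others. Nos2, encoding inducible nitric oxide synthase, was at 208 CPM in subclone 8 and 95.3 CPM in subclone 6, against 86.9 CPM in the library labelled 3H3P and at most 14 CPM in the other subclones. Agt, encoding angiotensinogen, was at 544 and 364 CPM in subclones 8 and 6 and at most 103 CPM in the others. H19 had 134 counts in subclone 7 and at most 5 elsewhere, and Xist had 215 counts in subclone 3 and at most 4 elsewhere. Lcn2, an acute phase gene, was at 2217 CPM in the library labelled 3H3P and 8.43 to 331 CPM in the subclones.

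Genes expressed in the library labelled 3H3P (CPM of 5 or more) and silent in every subclone (CPM under 0.5) numbered 129. Those under 0.5 CPM in that library and at 5 CPM or more in each of the 7 subclones numbered 28. The 2 counts are not like for like, since expression was asked of 1 library in the first and of 7 in the second. Among called genes, 89 had 0 counts in every subclone and 65 had 0 counts in the library labelled 3H3P. Cdkn2a was one of the 129, while its neighbour Mtap was at 113 CPM in that library and 138 to 318 CPM in the subclones. The chromosome 8 median, relative to the mean of the subclones, was 0.25, 0.10 and 0.23 log2 units in subclones 1, 2 and 3 and −0.11, −0.14, −0.16 and −0.17 in subclones 6, 7, 8 and 9. The same subclones parted on chromosome 15 (−0.17, −0.21 and −0.07 against 0.08 to 0.13) and chromosome 12 (0.07, 0.21 and 0.11 against −0.13 to −0.02). Chromosome 6 parted them too (−0.05, −0.15 and −0.05 against 0.03 to 0.14), as did X (−0.11, −0.19 and −0.06 against 0.03 to 0.14). Chromosomes 1, 3, 7 and 10 also parted them without overlap, whereas others, 5 and 11 among them, did not. Whether the subclones share a lineage was not tested. In the weighing that follows, the tests on the p53 targets, on the Il11-high subclones and on other splits were chosen after the results were seen. The host cell tests replaced a first version on other genes, which left macrophages open because of Csf1r.

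Genes of whole chromosomes were shifted together between the library labelled 3H3P and the subclones. Over 9865 genes with a mean CPM of 5 or more, 15 of 20 chromosomes passed, some with small shifts, and the median log2 fold change was 0.58 on chromosome 12 and −0.52 on chromosome 15, against 0.06 overall (each permutation p = 1e-04, the smallest that 10000 shuffles of chromosome labels can give, adjusted p = 0.000182; genes are not independent replicates). A GC content or length bias is argued against, since the medians were 0.60 and −0.53 after a loess correction for both. All 10 of 10 equal bins along each of the 2 lay on the side of its median, as they also did on chromosomes 3, 4, 5 and 7, so a shift of the whole chromosome, such as a copy-number difference, is a candidate explanation, untested in DNA. Mouse Myc lies on chromosome 15, but its log2 change of −3.71 is far larger than the shift.

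The p53 target list was higher in the library labelled 3H3P, where the labels state that p53 protein was lost (adjusted p = 0.000142, and adjusted p = 0.0823 with an estimated correlation). A general fall of genes at this expression level is argued against, since the list median lay at percentile 0 of 10000 matched random lists, and so are chromosome-wide shifts, with percentile 0 after chromosome medians were taken off. Retained p53 function in that library, from a mislabelled, mixed or partly edited culture, cannot be told apart from other differences between the groups, since no unedited 3H3 library was analysed here. That 16 of 26 targets (61.5%, against 30.4% of all tested genes) were lower in all 7 subclones restates the pattern and decides nothing. MYC and growth in mice stay open, untested.

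Among the subclones Il11, Cd274, Saa3 and Pdgfra were all highest in subclone 8 and next in subclone 6, while Saa3 was at 1193 CPM in the library labelled 3H3P, which had 2 Il11 counts. Host fibroblasts are argued against, since 11 of the other 14 fibroblast and stellate markers, Dcn, Lum and Dpt among them, had under 3 counts in both, although Pdgfrb was high in every subclone and Col1a1 was at 6.23 CPM or less. For host macrophages 11 of 15 markers had under 3 counts in both, including C1qa, C1qb and Tyrobp at 0. However, Cd68 (101 and 82 counts in subclones 8 and 6, at most 42 in the other subclones) and Cd74 (13 and 8, at most 4) follow the pattern. Csf1r had 317 and 212 counts in subclones 8 and 6, at most 222 in the other subclones and 185 in the library labelled 3H3P. The deciding markers of both host cell tests were picked after values were seen. A first version left macrophages open, so the counts give no verdict on them. A closer common origin of subclones 6 and 8 cannot be told apart, since their chi-square per degree of freedom of 17.7 may come from the shared expression itself. A STAT3-responsive programme that follows Il11 may be a biological explanation, with r = 0.923 over the other 5 subclones, but rank correlation did not pass after adjustment and the relation lost its call without single subclones. That r leans on subclone 2, the lowest of the 5 on both values. Saa3, a gene of the pattern, is itself a member of the STAT3 list, and no score without it was computed. Between the groups the STAT3 list went the other way, lower in the subclones than in the library labelled 3H3P. The pattern was not particular to the STAT3 list. The MAPK pathway output score, not among those set against Il11, was also highest in subclones 8 and 6 (4.98 and 4.97) and lowest in subclone 2 (3.72).

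With each of the 8 libraries in turn set against the other 7, the library labelled 3H3P gave 2799 called genes and the highest other library 2. Only 1 of 8 splits gave as many, and 8 splits are too few for a share under 0.05. In the other splits the library labelled 3H3P is among the 7 and widens their spread. With that library left out, each subclone against the other 6 gave 0 to 3 called genes.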
